A study of Homo sapiens with 6 samples.

How the data were processed

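The 6 libraries come from A549 cells, 1 library per condition and assay. Per the labels, input RNA was chemically fragmented and ribosome footprints were made with RNase I, both were size-selected on a gel, and the libraries were amplified by PCR; no molecular identifiers are named. The submitters' processing notes name cutadapt 2.8, Bowtie2 2.2.5, STAR 2.7.5c and featureCounts 2.0.1 with the genome build GRCh38, without their parameters.

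The deposited count table holds raw counts per gene, with no normalization, for 60648 genes in the 6 libraries, with a gene length beside each. A record broken over 3 lines names no usable gene and was left out. The authors also deposited, for each condition, TPM values (counts over gene length, scaled to a common total) and a translation efficiency. Tested on the files, each TPM value equals the count over the gene length, scaled to the sum over all genes of the table, small RNAs included, and the deposited tables keep protein-coding genes with an input TPM above 1. The deposited translation efficiency is the ratio of footprint TPM to input TPM of the same condition.

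Samples were grouped by shRNA, medium and assay as their titles give them. The comparisons were METTL16 knockdown against control shRNA, both starved, and starved against complete medium, both METTL16 knockdown; the starved knockdown libraries serve both, so the results of the comparisons were not correlated or overlapped. Counts were scaled with TMM factors from edgeR 4.0.16 (R 4.3.3), made over the 3 libraries of an assay, and log2 ratios were taken with a pseudocount of 0.5. Genes entered with a mean of at least 30 counts over the 3 libraries of each assay used, which left 3876 genes in input RNA, 3431 in footprints and 2866 in translation efficiency. Intervals at 95% come from the exact conditional binomial (Clopper-Pearson) for RNA and footprints and from the Poisson variance of the 4 log counts (delta method) for translation efficiency. Where an interval comes from resampling genes instead, the text says so. With 1 library per group no model has residual degrees of freedom, so no p-value was computed; genes that differ at least 2-fold with an interval excluding 0 were counted, beside the numbers from 20 binomial resamplings of the pooled counts. A log2 ratio with 1 to 3 counts on a side is given with its interval, and no fold is given where both sides are at or under 3 counts, which correspond to 3.25 to 6.61 TMM-scaled CPM over the libraries. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

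The calls were tested on simulated Poisson counts with the libraries' own depths and 200 changed genes per measure and comparison. Of genes set to a 4-fold change 99 to 100% were recovered, and of those set to exactly 2-fold, the cut of the call, 47 to 62%. Of unchanged genes 0.310 to 2.03% were called, and the intervals covered the true value in 94.8 to 96.2% of genes. The intervals assume the same Poisson error, so these values check the code and do not cover further error in PCR reads.

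The named genes follow a rule set before the data were examined, as were the gene lists, the comparisons and the alternatives not described as added. Among protein-coding genes past the minimum, leaving out mitochondrially encoded and histone genes, these are the 5 highest and 5 lowest in translation efficiency and the 4 highest and 4 lowest in input RNA and in footprints, ranked by the interval end nearest 0. METTL16, MAT2A, FAS, TNFRSF10A, TNFRSF10B, TNFRSF1A, TNFRSF21 and TNFRSF25 were named in any case, and from each list its 2 highest and 2 lowest members; some single-gene results are not reported here. Coordinates come from the RefSeq annotation of GRCh38.

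The 27 gene lists were METTL16 and the methionine cycle, m6A writers, readers and erasers, the extrinsic death receptor pathway, intrinsic apoptosis, the ATF4 amino acid response, cytosolic aminoacyl-tRNA synthetases, cytosolic ribosomal proteins, other TOP mRNAs, translation initiation factors, amino acid sensing and mTORC1, autophagy and lysosome, p53 targets, NRF2 targets, cholesterol synthesis, immediate early genes, NF-kB targets and cytokines, the interferon response, heat shock and protein folding, the cell cycle, replication-dependent histones, mitochondrially encoded mRNAs, nuclear oxidative phosphorylation, glycolysis and hypoxia, extracellular matrix and mesenchymal genes, alveolar and airway epithelial markers, fibroblast markers, and leukocyte and erythroid markers. ATF3, BIRC3, CTH, SESN1, SLC7A11 and VIM belong to more than 1 list. A list with at least 5 measured members was set against 10000 random lists of the same size matched on mean input expression in 20 bins; its percentile (outside 2.5 to 97.5 or not) describes these libraries only, since genes are not replicates. The draws left out no listed gene, so a list's own members can enter its random lists and pull the range toward it.

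The alternatives were DESeq2 1.42.0 size factors, total counts, a minimum of 10 or 100 counts or none, a pseudocount of 5, protein-coding genes alone, random lists without matching, and the deposited translation efficiency. Added after seeing the data were another library's input RNA in place of the starved knockdown's, the deposited translation efficiency divided by its median, a correction for the trend with gene length, total counts for the list medians, and the named genes under other settings. Across genes, the deposited and recomputed translation efficiency had a Spearman correlation of at least 0.999961 in each condition, which is fixed by construction up to rounding, and genes are not independent replicates.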

Results

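The series measured RNA and ribosome occupancy in A549, a human non-small cell lung cancer line, in which METTL16 was knocked down with an shRNA. METTL16 is an RNA methyltransferase known to modify U6 snRNA and the MAT2A mRNA. The cells were kept for 2 h in complete medium or in amino acid starvation medium and received cycloheximide, which stalls elongating ribosomes, for 5 min. Each condition gave an input RNA library and a library of ribosome footprints, the fragments that ribosomes shield from RNase. The 3 conditions were control shRNA starved, METTL16 shRNA starved and METTL16 shRNA in complete medium, with 1 library per condition and assay; control shRNA cells in complete medium were not analysed here. In the order control starved, knockdown starved and knockdown complete, the total counts were 537558, 465303 and 775676 for input RNA and 781831, 518955 and 711754 for footprints.

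There are no replicates, so no difference could be held against a replicate spread and no p-value is given. Every difference below compares single libraries, and its 95% counting interval covers counting error only, since PCR reads without molecular identifiers are not independent molecules. Values are log2 ratios after TMM scaling, a gene is called higher or lower when it differs at least 2-fold with an interval that excludes 0, and translation efficiency is the footprint level over the input RNA level. TMM scaling holds the typical gene near 0 and no spike-in gives an absolute scale. Higher and lower are therefore relative to the typical gene, and a change of all mRNAs alike would not show.

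METTL16 (ENSG00000127804.13, GRCh38 chromosome 17, 2415715 to 2511888) had a level of 77.0 in the input RNA of the starved control, 19.8 in the starved knockdown and 25.4 in the knockdown in complete medium, in CPM, counts scaled by the library's TMM-adjusted total. Its footprints stood at 65.0, 6.24 and 10.8 in the same order, from 60, 3 and 7 reads. Against the starved control, the starved knockdown had a METTL16 log2 ratio of -1.89 in input RNA (-3.18 to -0.90) and of -3.17 in footprints (-5.70 to -1.76). With these counts METTL16 lies below the count minimum and is not among the genes tallied. MAT2A (ENSG00000168906.13, chromosome 2, 85539168 to 85545281), the methionine adenosyltransferase whose mRNA METTL16 binds, was lower in the input RNA of the starved knockdown, at -0.66 (-1.08 to -0.26), and near 0 in footprints, at -0.02 (-0.32 to 0.27), or -0.37 when libraries are scaled by total counts. Its translation efficiency was higher by 0.64 (0.15 to 1.13), by 0.41 with total counts and by 0.28 when the input RNA of the knockdown in complete medium takes the place of the starved knockdown's. The methionine cycle list has 4 measured members, none called in this comparison in any measure, with a median translation efficiency change of -0.28.

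**Figure D1:**
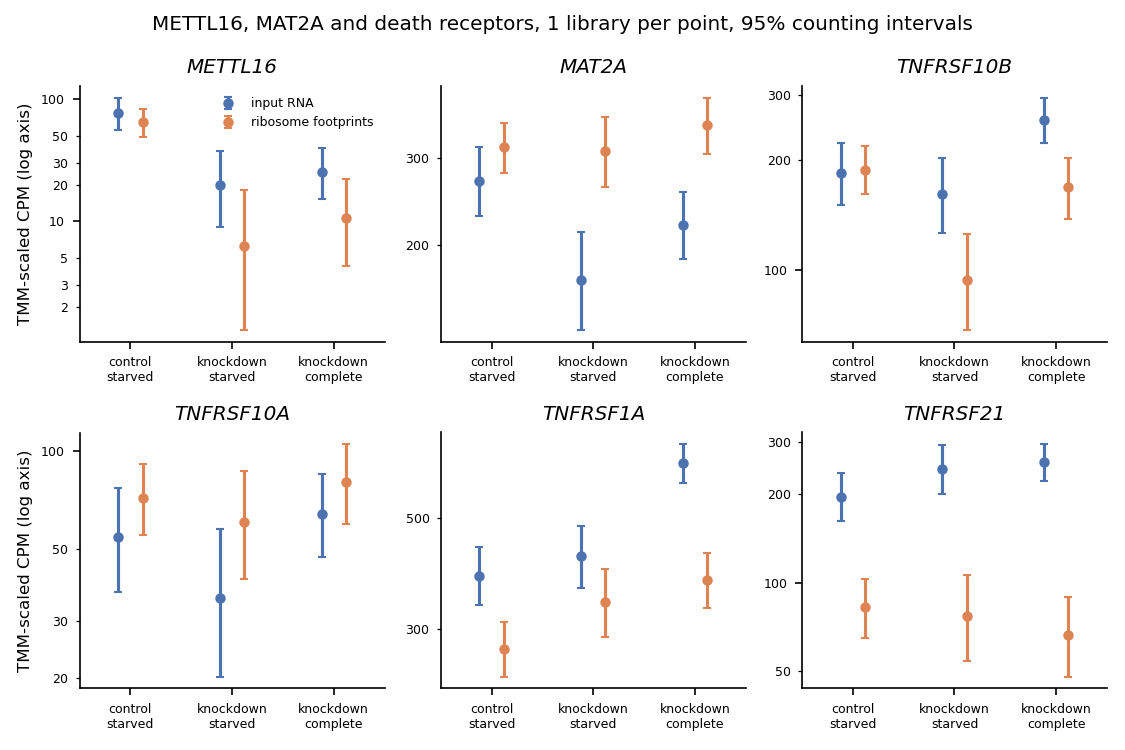
TMM-scaled CPM (log axis) of METTL16, MAT2A and 4 death receptors in the 3 conditions, input RNA in blue and ribosome footprints in orange; each point is 1 library and each bar its 95% counting interval. METTL16 input RNA goes from 77.0 in the starved control to 19.8 and 25.4 in the knockdown libraries, and TNFRSF10B footprints are at 93.5 in the starved knockdown against 187 in the starved control.

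The gene classes differed between libraries. Nuclear protein-coding genes took 82.6% of the counts of the starved control's input RNA, 77.0% in the starved knockdown and 77.5% in the knockdown in complete medium, and 79.0%, 64.4% and 66.0% of footprint counts (for the starved knockdown's footprints, an exact Clopper-Pearson 95% interval of 64.3% to 64.6%). Small nuclear RNAs made up 5.98% of the footprints of the starved control against 14.1% in the starved knockdown, and Y RNAs 9.08% against 14.6%. Mitochondrially encoded mRNAs made up 4.67% of footprint counts in the starved control, 5.26% in the starved knockdown and 9.95% in the knockdown in complete medium.

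**Figure D2:**
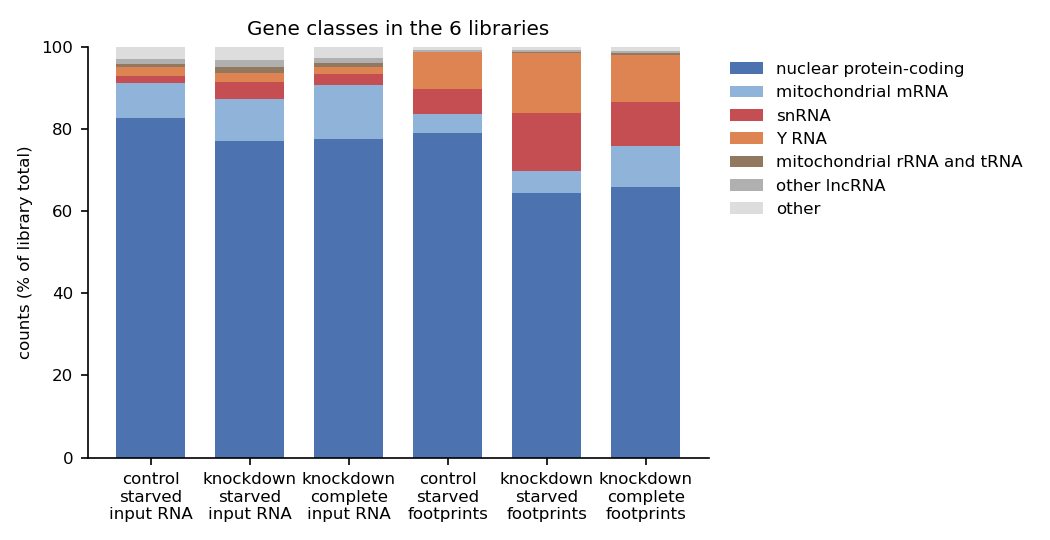
Share of the counts of each of the 6 libraries (percent of the library total) that falls on each gene class. The nuclear protein-coding share of footprints is 79.0% in the starved control, 64.4% in the starved knockdown and 66.0% in the knockdown in complete medium.

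The first comparison sets the starved METTL16 knockdown against the starved control. As control shRNA cells in complete medium were not analysed, it cannot tell a difference that depends on starvation from one present in both media. The death receptors are the genes named in the study's aim. Among them TNFRSF10B, which encodes the TRAIL receptor DR5, had fewer footprints in the knockdown, at -0.99 (-1.51 to -0.52), with input RNA at -0.19 (-0.64 to 0.25). The cholesterol synthesis list had higher medians in RNA and in footprints, and TM4SF4 and the neurotrophin receptor gene NTRK3 were higher in both. Vimentin (VIM), the intermediate filament gene of mesenchymal cells, was lower in RNA at -2.06 (-2.50 to -1.66) and in footprints at -1.91 (-2.51 to -1.39). The extracellular matrix and mesenchymal list it belongs to had medians of -0.04 and -0.06. In RNA 4 of 13 of its members were called lower, and in footprints 2 of 14 lower and 1 higher, CDH2 at 1.03, which lies under 2-fold with total counts.

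TNFRSF10B (ENSG00000120889.13, chromosome 8, 23020133 to 23069031) had 173 footprint reads in the starved control and 45 in the starved knockdown, and its translation efficiency was lower by a log2 ratio of -0.80 (-1.44 to -0.16), short of the 2-fold call. It passes 2-fold at -1.03 with total counts and at -1.47 with the replaced input, but neither adds support for a call. Total counts lower all genes alike, and the replaced input adds the gene's own RNA change between media, -0.67, to the reported value. In translation efficiency as reported, 296 of the 2866 genes measured had a lower value than TNFRSF10B, and in footprints 109 of 3431 did. Its translation efficiency level was 0.02 in the starved control (-0.32 to 0.37), -0.78 in the starved knockdown (-1.31 to -0.24) and -0.61 in the knockdown in complete medium (-0.95 to -0.27). TNFRSF10A, the other TRAIL death receptor, differed by -0.60 in RNA (-1.59 to 0.29) and by -0.23 in footprints (-0.93 to 0.41), or -0.58 with total counts. Its translation efficiency differed by 0.37 (-0.69 to 1.43), or -0.46 with the replaced input, so no difference was detectable in any measure at this depth. TNFRSF1A, the TNF receptor, stood at 0.31 in footprints (0.02 to 0.60), or -0.036 when libraries are scaled by total counts, and at 0.19 in translation efficiency (-0.21 to 0.58), or -0.040 with total counts and -0.43 with the replaced input. TNFRSF21 differed by -0.39 in translation efficiency (-1.07 to 0.28), or by -0.62 with total counts and -0.47 with the replaced input. FAS had 10 input reads in each of the starved libraries and 26 against 16 footprint reads, below the minimum, and TNFRSF25 had no read in any library, so neither is compared. The extrinsic death receptor list had 7 measured members in translation efficiency, with a median of -0.20, and 1 was called lower, CFLAR, the caspase-8 inhibitor FLIP, at -1.76 (-2.75 to -0.76), while its input RNA was called higher at 1.23 (0.51 to 2.01) and its footprints stood at -0.53 (-1.34 to 0.19).

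Cholesterol synthesis genes had a median of 0.76 in input RNA over 16 measured members, of which 6 were called higher and 0 lower, and of 0.55 in footprints over 17 members, of which 7 were higher and 0 lower. IDI1 was at 1.39 (0.77 to 2.05) in RNA, and MSMO1 at 1.21 (0.85 to 1.57) in footprints. Both medians lie above the central 95% of random lists matched on expression, and their translation efficiency had a median of 0.02. Immediate early genes had a median of 0.44 in footprints, with 1 of 17 called higher, ZFP36, an mRNA decay factor, at 1.30 (0.76 to 1.85), and the list also lies above its random range. Cell cycle genes had a footprint median of -0.28, with 0 of 22 called and AURKA lowest at -0.96, and p53 targets an RNA median of 0.57, with 1 of 7 called, RRM2B at 1.15. Amino acid sensing and mTORC1 genes had an RNA median of -0.41, with 1 of 12 called lower, MLST8 at -1.17. The last 3 medians also lie outside their random ranges, those of p53 targets and of amino acid sensing only with the count minimum of 30 and not with 10. Genes of the ATF4 amino acid response had a median translation efficiency change of 0.41, with 5 of 21 called higher, among them PYCR1, a proline synthesis gene, HERPUD1 at 1.26 and, named after its value was seen, ATF4 itself at 1.08 (0.28 to 1.88). That list's median is -0.018 when the input RNA of the knockdown in complete medium takes the place of the starved knockdown's. Ribosomal protein mRNAs had medians of -0.03 in footprints (0 of 67 called) and -0.10 in translation efficiency (1 higher, 4 lower), both below their random ranges but inside those of unmatched lists (percentiles 28.6 and 16.2), the latter 0.13 with the replaced input. The other mRNAs with a 5' terminal oligopyrimidine tract (TOP), which mTORC1 controls, had a footprint median of -0.16 with 2 of 21 called lower, VIM and PABPC1, at -1.04, below its random range but inside that of unmatched lists. With total counts the footprint medians are 0.20 for cholesterol synthesis, 0.094 for immediate early genes, -0.63 for the cell cycle, -0.38 for ribosomal proteins and -0.51 for the other TOP mRNAs. The translation efficiency medians are then 0.19 for the ATF4 response and -0.32 for ribosomal proteins. Among the members with a value above, ZFP36 and MSMO1 then lie under 2-fold in footprints and ATF4 in translation efficiency, while AURKA lies beyond 2-fold in footprints.

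The genes furthest from 0 in translation efficiency, by the interval end nearest 0, were SPTBN1, a spectrin, at 2.34 (1.36 to 3.32), POLR2A, the catalytic subunit of RNA polymerase II, at 2.01 (1.20 to 2.81), SAMD4B at 1.89, CYBC1 at 1.94 and the laminin gene LAMA5 at 1.41. At the other end stood HELLS, a chromatin remodeller, at -2.53 (-3.53 to -1.53), ERGIC2 at -2.48, the ESCRT gene CHMP2B at -2.17, RBPMS at -2.19 and MAP7 at -2.23. In each of these 10 genes input RNA and footprints lay on opposite sides of 0, which ranking on their difference favours by itself. POLR2A had -1.56 in RNA and 0.45 (-0.10 to 0.98) in footprints, and HELLS 1.35 and -1.18. The footprint interval of MAP7 (-1.96 to 0.05) holds 0 as that of POLR2A does. LAMA5 footprints, at 0.35 (0.02 to 0.66), fall just below 0 with total counts. In input RNA, NTRK3 was at 2.16 (1.45 to 2.97), the phosphodiesterase gene PDE3A at 1.99, SEZ6L2 at 2.65 and TM4SF4 at 2.05, against CD70, a TNF family ligand, at -2.44 (-3.45 to -1.65), SSR2 at -2.24 and MARVELD1 at -2.65. In footprints NTRK3 was at 3.07 (2.38 to 3.87), TM4SF4 at 2.32, the fatty acid desaturase gene SCD at 1.56 and CPLX2 at 1.73. CRIP2 was at -3.49 from 3 against 75 reads (-6.01 to -2.10), SSR2, a subunit of the translocon-associated complex, at -2.54, CDCP1 at -2.97 and OLFML3 at -2.95. IL6 had 20 footprint reads against 200 in the starved control, at -2.35 (-3.12 to -1.72). The epithelial marker list had CDH1, E-cadherin, at 1.52 in RNA and 1.70 in footprints as its 1 called member of 6 and of 5, and the fibroblast and the leukocyte and erythroid lists had 0 measured members.

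In all, 195 genes were called higher and 177 lower of 3876 in input RNA, 136 and 104 of 3431 in footprints, and 140 and 157 of 2866 in translation efficiency, where resampling the pooled counts gave on average 5.65 and 7.45, 1.70 and 7.10, and 20.5 and 20.6. These tallies include genes that are not protein-coding. With protein-coding genes alone, 100 were called higher and 97 lower of 3357 in footprints, of which 98 and 97 are among those just counted. Scaling by total counts moved the all-gene median by -0.12 in RNA, -0.35 in footprints and -0.23 in translation efficiency and gave 133 and 236, 57 and 323, and 71 and 314, and with the input RNA of the knockdown in complete medium 154 and 195 genes were called in translation efficiency, of which 53 and 70 were called the same way before.

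The second comparison sets starved against complete medium within the METTL16 knockdown and asks what amino acid starvation does in these cells. Relative to the typical gene, ribosomal protein and other TOP mRNAs as groups had fewer footprints in starved cells without having less RNA. Ribosomal protein mRNAs had a median of -1.23 in footprints and 0.33 in input RNA. PABPC1, the poly(A)-binding protein, was at -4.26 in translation efficiency (-5.21 to -3.31), and the elongation factor gene EEF1A1 at -3.17 (-3.51 to -2.82). Targets of NF-kB and immediate early genes had higher medians in RNA and in footprints on the same relative scale, with ZFP36 at 2.19 in RNA and 3.28 in footprints and the chemokine gene CXCL8 at 2.11 and 2.01.

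Of 67 ribosomal protein mRNAs measured in translation efficiency, 51 were called lower, 0 higher and 0 lay above 0, with a median of -1.50 against a random range of -0.22 to 0.22. RPL7 was at -3.24 and RPSA at -2.90, and RPL29 was nearest 0 at -0.32. All 20 of the other TOP mRNAs measured were called lower, with a median of -1.85, EEF2 at -2.94 (-3.17 to -2.71) and NOP53 nearest 0 at -1.19. In footprints 48 of 67 ribosomal protein mRNAs and 17 of 21 other TOP mRNAs were called lower. In input RNA 60 of 75 ribosomal protein mRNAs lay above 0, with 1 called, RPS12 at 1.08, and the other TOP list had a median of 0.46 with 4 of 22 called higher, NAP1L1 at 1.25 and NACA at 1.13 first. Relative to the median of all genes, the translation efficiency level of ribosomal protein mRNAs was -0.17 in the knockdown in complete medium, -1.73 in the starved knockdown and -1.60 in the starved control, and that of the other TOP mRNAs 0.38, -1.37 and -1.30. VIM belongs to the TOP list and to the extracellular matrix and mesenchymal list.

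**Figure D3:**
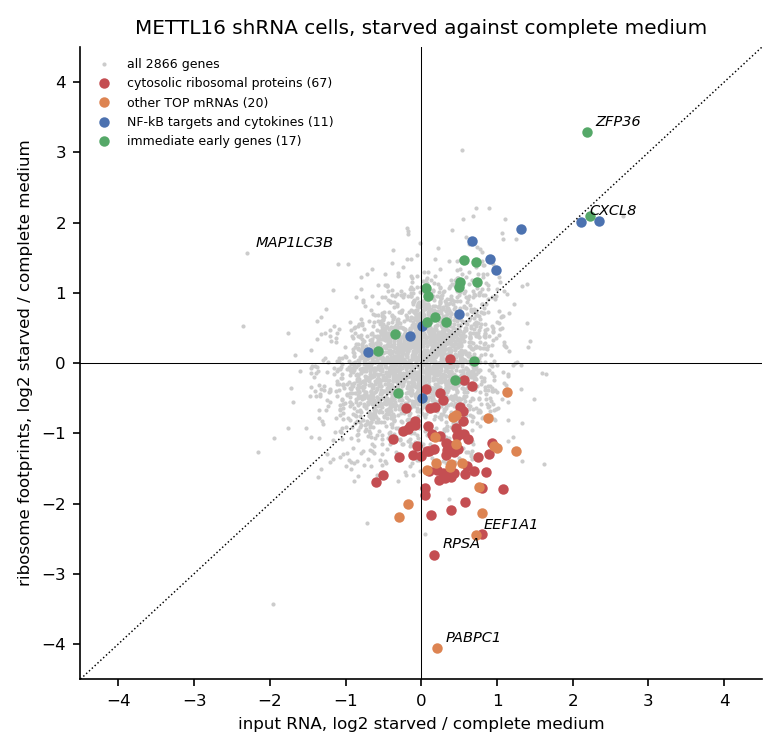
Log2 ratio of starved to complete medium in the METTL16 knockdown, input RNA on the x axis and ribosome footprints on the y axis, for 2866 genes; each point is 1 gene, colours mark 4 gene lists, and the dotted line marks equal change. Ribosomal protein and other TOP mRNAs lie below the line, down to PABPC1 at -4.06 in footprints, and NF-kB targets and immediate early genes lie mostly to the upper right, up to ZFP36 at 3.28.

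NF-kB targets and cytokines had a median of 0.67 in input RNA, with 5 of 15 called higher, among them CXCL2 at 2.39 (1.71 to 3.17) and TNFAIP3, a feedback inhibitor of NF-kB, at 2.35. Their footprint median was 1.40, with 7 of 12 called higher, among them TNFAIP3 at 2.02 and IL6 at 2.62 from 20 against 4 reads (1.18 to 4.76). Their translation efficiency median was 0.51, with 1 of 11 called higher, CXCL1 at 1.07. Immediate early genes had medians of 0.39 in RNA, with 2 of 18 called higher, 0.95 in footprints, with 8 of 17, and 0.57 in translation efficiency, with 2 of 17. KLF6 was at 2.22 in RNA and 2.09 in footprints. Replication-dependent histone genes, which the nucleosome core and linker proteins come from, had a footprint median of 0.83 with 4 of 14 called higher, H1-5 at 1.42 and H2AC20 at 1.25. Mitochondrially encoded mRNAs had a footprint median of -0.96 with 5 of 12 called lower, MT-ND3 at -1.46 and MT-ATP6 at -1.35, and a translation efficiency median of -0.67, inside its random range. That range is drawn from genes of like expression with no listed gene left out, so lying inside it decides little. Aminoacyl-tRNA synthetases had a translation efficiency median of -0.44 with 4 of 18 called lower, EPRS1 at -1.86 and QARS1 at -1.42. Extracellular matrix and mesenchymal genes had medians of -0.61 in RNA, with 5 of 13 called lower, COL4A2 at -1.08 and ITGA5 at -1.09 lowest, and of -0.52 in footprints, with 2 of 14 lower, VIM at -1.43 and fibronectin (FN1) at -1.29, and 1 higher, ITGA5 at 1.41. Nuclear genes of oxidative phosphorylation had an RNA median of 0.28 with 0 of 30 called. Autophagy and lysosome genes had a translation efficiency median of 0.51 with 4 of 11 called higher, MAP1LC3B, which coats autophagosomes, and the lysosomal protease CTSD at 1.17. Over both comparisons 29 of 138 medians lay outside the central 95% of their random lists, where 6.9 would be expected of independent medians of unrelated genes. The measures, lists and comparisons share libraries and genes, and genes of a list can move together, so 29 against 6.9 is not a test. The medians in this paragraph lie outside their random ranges unless stated otherwise. But those of NF-kB targets and of autophagy in translation efficiency, of oxidative phosphorylation in RNA and of the matrix list in footprints do so only with the count minimum of 30 and not with 10. Those of NF-kB targets and autophagy in translation efficiency also lie inside the ranges of unmatched lists. The translation efficiency median of immediate early genes lies inside its range with the replaced input, at 0.46. The ATF4 response list, at 0.40 in translation efficiency, lies inside its range.

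**Figure D4:**
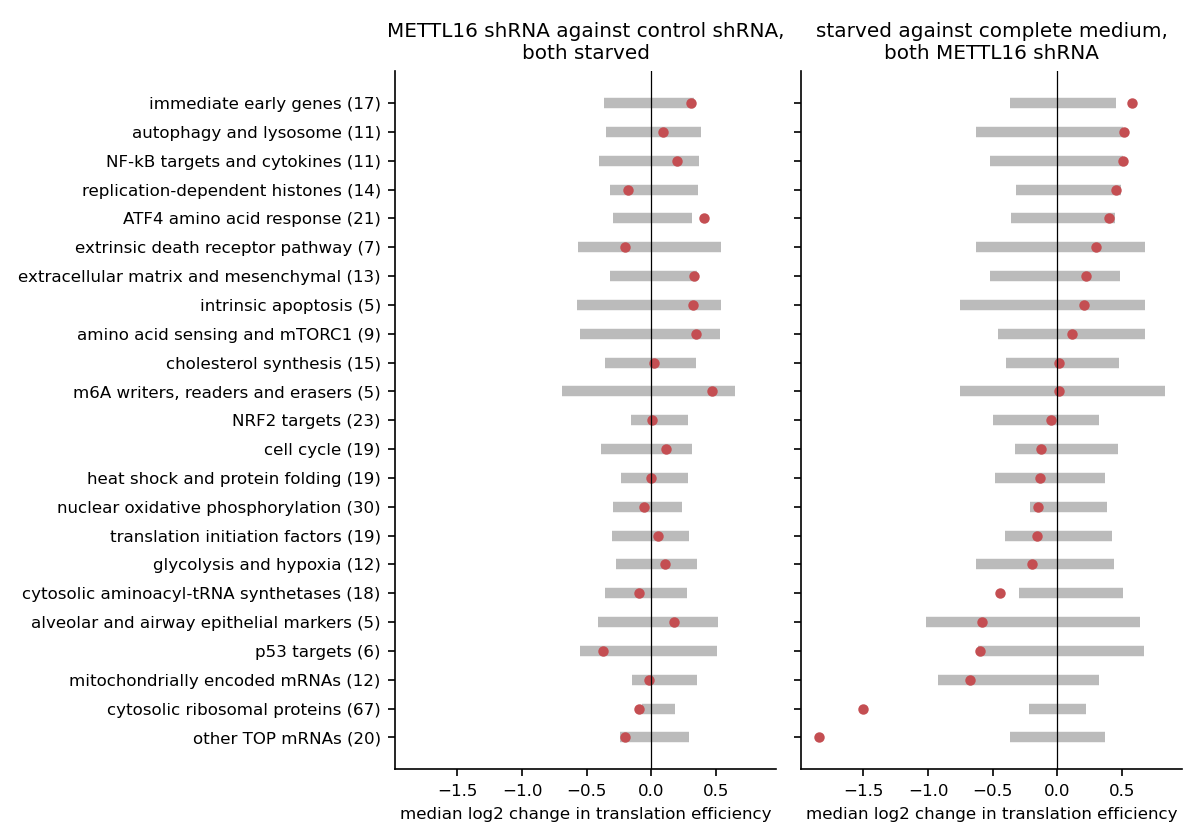
Median log2 change in translation efficiency of 23 gene lists (red points; measured members in brackets) beside the central 95% of random lists of the same size matched on expression (grey bars), for the knockdown against control shRNA, both starved (left), and for starved against complete medium, both knockdown (right). Ribosomal protein mRNAs at -1.50 and other TOP mRNAs at -1.85 lie far below their bars on the right, and on the left the ATF4 response at 0.41 lies above its bar, though at -0.018 with the replaced input.

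MAP1LC3B ranked first in translation efficiency, at 3.87 (3.02 to 4.71), from 41 against 337 input reads and 51 against 23 footprint reads. CTC1, of the telomere-capping CST complex, was at 2.88, the proteoglycan gene SDC1 at 2.21, COX8A at 2.06 and CTSZ at 1.98. MAP1LC3B, LEMD2, CTC1 and MARVELD1 were the lowest in input RNA, at -2.30, -2.70, -2.35 and -2.82, and the kinase gene PIM1 was at 2.66 (1.83 to 3.66). In footprints ZFP36L1, a relative of ZFP36, was at 1.77 (1.38 to 2.17) and the antiproliferative gene BTG1 at 2.09, against PABPC1 at -4.06 (-5.28 to -3.18), RPSA at -2.73, EEF1A1 at -2.45 and EEF2 at -2.14. Among the death receptors TNFRSF10B was lower in RNA at -0.67 (-1.08 to -0.28) and in footprints at -0.83 (-1.38 to -0.33), with translation efficiency at -0.17 (-0.80 to 0.46). TNFRSF1A was lower in RNA at -0.62 (-0.87 to -0.37) with translation efficiency at 0.47 (0.10 to 0.85), TNFRSF10A was at -0.83 in RNA (-1.78 to -0.02), and TNFRSF21 was at 0.22 in footprints (-0.46 to 0.89). METTL16 differed by -0.31 in RNA (-1.68 to 0.86) and MAT2A by -0.36 (-0.78 to 0.03).

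In all, 117 genes were called higher and 161 lower in input RNA, 185 and 231 in footprints and 198 and 274 in translation efficiency, against 3 and 5.90, 5.25 and 9.70, and 21.5 and 20.7 on average when the pooled counts were resampled. With the starved control's input RNA in place of the starved knockdown's, 326 genes were called higher and 296 lower in translation efficiency, of which 110 and 176 were called the same way before; ribosomal protein and other TOP mRNAs then had medians of -1.54 and -1.72.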

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

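The tests of gene length bias and of reads moved to pseudogenes were set before their results were seen, and the other tests in this part were chosen only afterwards. The test of short mRNAs replaces one set beforehand with lists matched on annotated gene length, which is not that of the mRNA, and its limit and the omission of histones were set after values at several limits were seen. Small nuclear RNAs and Y RNAs are not mRNAs, though those past the count minimum enter the gene tallies. They took a larger share of footprint counts in both knockdown libraries than in the starved control. Small nuclear RNAs made up 14.1% of the footprint counts of the starved knockdown and 10.6% of those of the knockdown in complete medium, against 5.98% in the starved control. Y RNAs made up 14.6% and 11.6% against 9.08%. In input RNA small nuclear RNAs made up 4.05% and 2.57% against 1.71%, and Y RNAs 2.28% and 1.82% against 2.10%, so the Y RNA share of the complete medium input is the smaller one. Each share is 1 library, so none could be held against a replicate.

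The deposited translation efficiency is lower in the starved knockdown than in the starved control, with medians of 0.263 and 0.400, a log2 change of -0.60. The share of nuclear protein-coding genes in the TPM totals, of which the short Y RNAs and small nuclear RNAs fill 77.0% in the starved control's and 87.4% in the starved knockdown's footprints, changed by -0.53 (footprints minus input) and makes up 88.4% of that change. That follows nearly by construction of a ratio of TPM, and a loss of mRNA footprints would give the same. A uniform loss would raise every small RNA family alike against mRNA, and between starved libraries the families with at least 1000 footprint reads, a limit set after the values were seen that leaves out U6, were higher by factors from 1.25 (U2) to 4.76 (U5), which differ 3.82-fold, but in input RNA the same families were already apart, from 1.15 (RNY5) to 4.18 (U5). A loss of mRNA footprints in the knockdown cells and a larger share of small RNA carried into the 30 nt gel region cannot be told apart, since no spike-in gives an absolute scale.

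Between the starved knockdown and the starved control, 297 genes differ in translation efficiency, 237 more than the 60 that the highest resampled counts add up to, but reads without molecular identifiers can hold more counting error than resampling does, so counting error stays open. A trend of the median with annotated gene length does not account for most of these calls, since 92.3% of these genes were still called after correction for it. The annotated length is not that of the mRNA, so bias by mRNA length stays open. In the called genes the input RNA of the knockdown in complete medium lies 65.3% of the way from the starved knockdown to the starved control. The interval of 53.1 to 73.5 comes from resampling genes 2000 times and gives a spread across genes only. These genes were called partly on the starved knockdown's own input, which by itself moves another input toward the control, and the medium differs as well. The position therefore decides nothing, and a fault of that input and a difference of knockdown cells cannot be told apart. GC content was not tested, as no genome sequence was used here, and METTL16 knockdown itself stays open as an explanation.

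Ribosomal protein and other TOP mRNAs have lower translation efficiency in the starved than in the complete medium knockdown. Short mRNAs as the whole cause are argued against by 28 other genes, histones left out, whose annotated exons add up to at most 1000 bases, with a median of 0.35 (0.093 to 0.54) against -1.50 (-1.70 to -1.30) for ribosomal protein mRNAs. Both intervals come from resampling genes and give the spread across genes in these libraries, not a replicate error. The 28 genes were not matched on expression and their limit was set after values were seen, so they weigh less than a test set beforehand. Reads moved to pseudogenes are argued against by footprints on pseudogenes of the listed genes that are themselves lower, at -1.52 (-1.74 to -1.29). A fault of the starved knockdown's footprints alone is argued against by the starved control, in which 87 of the listed genes lie -1.55 from their level in the complete medium library (random range -0.27 to 0.087). It stays open that 1 library stands for complete medium; a lower translation of TOP mRNAs under amino acid starvation, as mTORC1 is known to impose, may be the cause and remains a hypothesis.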

How the results depend on the processing

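The replaced input, the median-divided deposited values, the length correction, the total counts for list medians and the named genes under other settings were alternatives chosen after seeing the data, and the others were set beforehand. Counts below are genes called higher and lower, first for input RNA, then footprints, then translation efficiency; the knockdown comparison comes first and the medium comparison after it. With DESeq2 size factors and with protein-coding genes alone all 12 counts stayed within 1.5 times. Protein-coding genes alone took the footprint genes called higher in the knockdown comparison from 136 to 100. The filter changes how many genes are measured, and the counts with it: with at least 10 counts they were 572 and 507, 413 and 343, 431 and 426, then 458 and 434, 521 and 497, 509 and 573. With at least 100 counts they were 43 and 20, 48 and 11, 11 and 8, then 16 and 33, 41 and 70, 28 and 71. Without a filter they were 881 and 645, 820 and 479, 738 and 591, then 779 and 564, 702 and 672, 698 and 772. Total counts gave 57 and 323 in footprints and 71 and 314 in translation efficiency of the knockdown comparison, by construction of the shift of -0.35 and -0.23 in the all-gene median. A pseudocount of 5, which shrinks low counts, gave 105 genes lower in input RNA and 50 in footprints for the knockdown and 88 in input RNA for the medium. The deposited translation efficiency gave 15 and 714 for the knockdown, and 152 and 161 once divided by its median. The replaced input gave 326 higher for the medium, 52.4% of its calls against 41.9%. The length correction gave 131 and 166 for the knockdown, of which 124 and 150 were called before, and 196 and 278 for the medium. The agreement of deposited and recomputed values was at least 0.999961 with either scaling.

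A value is called reversed when it has the other sign under an alternative and its interval excluded 0, or its list median lay outside the random range, in the analysis as reported; values with an interval that holds 0, as TNFRSF1A (-0.43) and TNFRSF10A (-0.46) in translation efficiency, are not counted. With the replaced input, translation efficiency in the knockdown comparison reversed for the ATF4 response list (-0.018) and ribosomal proteins (0.13), and for RRM2B (0.59), PGK1 (0.018), ABCC3 (-0.0071), TNFAIP3 (1.49), NARS1 (0.037), MAP1LC3B (-1.06), CXCL8 (1.33), CDH2 (-0.10), H1-5 (-0.18), MT-CO2 (-0.025), VARS1 (-0.30) and MUC5AC (-0.20), and in the medium comparison for FDFT1 (0.063). With total counts the knockdown comparison reversed for TNFRSF1A (-0.036) and MT-ATP8 (-0.11) in footprints and MT-CO2 (-0.059) in input RNA. LAMA5 footprints then fall just below 0 too, but LAMA5 was named for translation efficiency and only that value was tallied. The reversals follow from how the settings are built. Replacing the input shifts each gene by its own input RNA difference between the exchanged libraries, and total counts shift all genes of a measure alike. Whether the medium, the shRNA or a single library lies behind those input differences was not tested. Of 138 list medians, DESeq2 size factors moved 0, a minimum of 10 counts 14, unmatched random lists 9 and total counts 20, and the replaced input moved 12 of 46 besides the 2 reversed. Unmatched random lists put the ribosomal protein lists of the knockdown comparison inside their range (percentiles 28.6 in footprints and 16.2 in translation efficiency). Of 644 single values, DESeq2 size factors and a pseudocount of 5 moved 0 and total counts 29, and the replaced input moved 52 of 219. No replicate could be left out and no paired test run, since each group is 1 library. Depth limits what can be seen, with median half-widths of the counting intervals from 0.56 to 0.74. The self-test recovered 47 to 62% of genes set to exactly 2-fold, but that is the cut of the call, so this share does not measure depth.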

Other observations

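The list medians in this part were set beforehand, and the values with total counts were chosen after seeing the data. In the knockdown comparison the NRF2 targets, antioxidant genes active in A549, had a median of 0.29 in input RNA with 0 of 24 called, 11 with an interval above 0, AKR1B10 at 0.89 and AKR1C2 at 0.83 first, and 4 with an interval below 0, FTH1 at -0.80 and FTL at -0.52 lowest, and the median lies inside its random range. Mitochondrially encoded mRNAs had an RNA median of 0.41 with 12 of 12 above 0, though MT-CO2 lies at -0.059 with total counts. Their footprint median was 0.48 with 1 called, MT-ND1. With total counts the footprint median is smaller, MT-ND1 lies under 2-fold, MT-ATP8 at -0.11 and MT-ATP6 below 0. Intrinsic apoptosis genes had an RNA median of 0.24 with 2 of 9 called higher, PMAIP1 (NOXA) at 1.28 and cytochrome c (CYCS) at 1.25, and CYCS was lower in translation efficiency, at -1.50 (-2.21 to -0.78). Replication-dependent histone genes had a footprint median of -0.21 with 0 of 14 called. The m6A list had an RNA median of -0.02 with 1 of 5 called lower, the reader YTHDF3 at -1.12. Initiation factors had an RNA median of -0.19 with 0 of 22 called and a footprint median of -0.08 with 1 of 23 called lower, EIF5 at -1.38. Heat shock and protein folding genes had a footprint median of 0.20, below 0 with total counts. Of 20 members XBP1 was called higher at 1.15, under 2-fold with total counts, and SDF2L1 lower at -1.38. Glycolysis and hypoxia genes had a footprint median of 0.12, below 0 with total counts, with 1 of 13 called higher, ADM at 1.73. Interferon response genes had 2 measured members, neither called.

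In the medium comparison intrinsic apoptosis genes had an RNA median of 0.41 with 3 of 9 called higher, PMAIP1 at 1.27 and BIRC3 at 1.25 first, and CYCS was at 1.66 in footprints. Cell cycle genes had a translation efficiency median of -0.13, with 3 of 19 called higher, CCNB2 at 1.54 and AURKB at 1.48 first, and 1 lower, TOP2A at -1.39. Heat shock and protein folding genes had a translation efficiency median of -0.14 with 4 of 19 called lower, HSPA8 at -1.75 and HSPD1 at -1.63 first, and PDIA3 higher at 1.10. Among initiation factors EIF4EBP1, which mTORC1 phosphorylates, was at 1.59 in translation efficiency and EIF3A at -1.98, with 1 of 19 called higher and 3 lower. NRF2 targets had a translation efficiency median of -0.05 with 2 of 23 called lower, the ferritin gene FTL at -1.39 and TKT at -1.22. Of the p53 targets CCNG1 was at -2.31 and AEN at 1.60 in translation efficiency, with 1 of 6 called higher and 3 lower. Cholesterol synthesis genes had medians of -0.09 in RNA and -0.13 in footprints, with INSIG1, which holds back sterol synthesis, the 1 of 17 called in footprints, at 1.59. The epithelial marker list had a footprint median of -0.37 with 1 of 5 called lower, MUC5AC at -1.47.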
